A study of Rattus norvegicus with 8 samples.

How the data were processed

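The series matrix held 1 value per feature for each of 8 two-channel arrays, 4 of RIE cells and 4 of RIE-Ras cells, with no missing value among 20500 features. Per the labels, the deposited value is a fold change of the TGF-beta-1 treated signal over the control signal of one array, with control RNA in channel 1 and treated RNA in channel 2. The deposited values are on a log2 scale, as found from the values: the fold change that each gives is a whole multiple of 0.01 within a tolerance of 0.01 of that step for 100% of values. Dyes, scanner, background correction, within-array normalization and spot filter are not given in the sources used here, no dye swap is stated, and no intensities were used, so a feature's dye effect is not separable from the treatment within a line. It cancels in the contrast between lines if it is the same on all arrays. Direction is taken from the labels, and the scale from the values; whether the authors centred the values is unknown, and the medians of all 8 columns lay above 0.

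Features were named through the platform annotation given with the data, with symbols updated through the gene table of assembly GRCr8, from which no coordinates were used. One symbol was found for 12750 features, several for 5 and none for 7745, which stayed unnamed; 12720 symbols came through a gene identifier and 7 through an accession, and 23 were kept as given. Each array was centred on its median, and features of one symbol were averaged, which left 17402 features, 9652 of them named; 2266 symbols lay on more than 1 feature. Skil and Ccnd1 were not measured under these names.

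All 8 arrays were fitted together in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with one mean per line tested against 0 and the contrast RIE-Ras minus RIE. Tests were two-sided, with Benjamini-Hochberg adjustment over all features of a comparison and a threshold of 0.05. The residual degrees of freedom were 6 and the prior degrees of freedom 2.71. The SE given for a gene is the moderated one of this fit. It rests on a spread per feature that both lines share, so it is not the SE over the 4 arrays of a line. Gene lists, 19 in all with 534 entries of which 417 were measured, were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over the lists of a comparison. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule started, per comparison, from named features past the threshold with one sign on every array. Of these it took up to 10 rises and 10 falls with the largest mean change. If none passed, it took the 5 rises and 5 falls with the smallest p. It also took up to 4 members of each list with the smallest p. Where measured, a fixed set of genes was added, with Smad7, Skil, Junb, Klf10, Id1, Ptgs2, Ccnd1, Myc and Tgfb1. Of the list members and the fixed set the text names only a part in each comparison, and the rule did not choose that part. A further gene of that set and 1 of the 19 lists are not reported here.

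The fit was tested on simulated data for 17402 features with the residual spread of the real ones, 50 features changed at each of 4 sizes. In the simulated comparison of RIE cells, 20% of features changed by 0.5 on the log2 scale were recovered, 68% at 1, 96% at 2 and 92% at 3, with 12 false among 150 calls. For RIE-Ras cells these shares were 12%, 62%, 96% and 92%, with 5 false among 136 calls, and for the difference between lines 2%, 40%, 90% and 86%, with 7 false among 116 calls. Of 19 simulated lists of 25 genes, camera with the preset correlation called the 1 that was shifted by 0.5 and no other. The simulated genes were independent, so this does not test the calls for lists whose genes vary together. For the same reason the recovered shares and the false calls need not hold for the real features. The real arrays also differed in spread (SD from the median absolute deviation), from 0.24 on RIE replicate 2 to 0.55 on RIE replicate 4. RIE replicates 3 and 4 correlated across features with r = 0.688. Estimated correlations in the real lists ran from -0.0239 (apoptosis regulators) to 0.639 (respiration), with 0.393 for ribosomal proteins and 0.147 for TGF-beta and Smad early targets.

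The alternatives were no centring, equal spread per array, quantile normalization, each probe on its own, leaving out features at repeated fold values, log2 ratios limited to between -3 and 3, robust eBayes, array weights, each line fitted alone, an adjusted p under 0.10, the replicate number as a block, and leaving out each array. A repeated fold value was one listed more often than its neighbouring hundredths, which stood in for a filter on dim spots. Correcting each array by the median of 35 position blocks, and averaging RIE replicates 3 and 4, were added after seeing the data. The feature numbers were taken as positions in rows of 215, which was inferred from the values.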

Results

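The response of rat intestinal epithelial cells to transforming growth factor beta 1 (TGF-beta-1), a growth-inhibitory cytokine that signals through Smad transcription factors, was measured on 8 two-channel arrays. RIE is a line of rat intestinal epithelial cells, and RIE-Ras cells carry in addition a stably expressed H-Ras activated by a mutation at residue 12. Each line had 4 arrays, and every array compared cells given 2 ng/ml TGF-beta-1 for 1 hr with control cells, so each value is a log2 ratio of treated over control RNA. The arrays held 20500 features, and 17402 remained after features of one gene symbol were averaged, 9652 of them named genes. Before centring, the array medians lay between 0.20 and 0.45 on the log2 scale, and all values below are relative to the median of their array. The number of arrays limits the precision. The labels number the samples and experiments of each line from 1 to 4 but do not say whether they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

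The first comparison asked which transcripts TGF-beta-1 changed within 1 hr in RIE cells. Smad7, the inhibitory Smad that TGF-beta induces as feedback, rose by 1.80 ± 0.19 (log2 ± SE, n = 4), a 3.48-fold change. Gadd45b, a stress and growth-arrest gene, rose by 1.67 ± 0.21. Among the falls were Gstp1, a glutathione transferase, at -2.06 ± 0.27, Plk2, a polo-like kinase, at -0.97 ± 0.12, and Rgs2, a regulator of G protein signalling, at -0.87 ± 0.11. The ribosomal protein genes Rpl32 (-1.75 ± 0.21), Rpl27 (-1.73 ± 0.16), Rps24 (-1.47 ± 0.17) and Rplp0 (-1.04 ± 0.13) fell, as did Nudc (-1.35 ± 0.14) and Coa4 (-0.73 ± 0.10), and the features averaged for Nudc, Rpl27, Rplp0 and Rgs2 differed in size. Averaged over its features, each named gene among these 13 calls had the same sign on all 4 RIE arrays. On RIE replicate 1, however, the features of Nudc (0.228 and -3.428) and of Rplp0 (-2.038 and 0.048) had opposite signs. In limma 13 features passed, 3 higher and 10 lower, 2 and 9 of them named, with adjusted p between 0.0345 and 0.0493, and 3052 features had an unadjusted p under 0.05 where 870.1 were expected. The count became 30, 0, 3 and 0 without RIE replicates 1, 2, 3 and 4, 3, 0, 1 and 0 without RIE-Ras replicates 1, 2, 3 and 4, which enter the shared spread, and 1 when RIE cells were fitted alone. Of the 13 calls, 7 were among the 30 without RIE replicate 1, and 1 was among the 3 without RIE replicate 3. Without centring, 4061 features passed, 3963 of them higher, since the median feature then stood at 0.35, and with equal spread per array 87 passed, 16 of them higher.

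Of the 26 measured members of the list of TGF-beta and Smad early targets, 20 had positive mean ratios in RIE cells, and the list was higher than other genes (median 0.23, camera adjusted p = 0.000105), which did not hold with an estimated correlation (adjusted p = 0.435). Its median was 0.55 on RIE replicate 1 and 0.05 to 0.25 on the other arrays, and 0.09 without that replicate. The count of members past the threshold was 2 over all features and 7, all higher, adjusted over the list alone. Bhlhe40, a transcriptional repressor, stood at 1.51 ± 0.24 (adjusted p = 0.0650) and Junb, an AP-1 subunit, at 1.77 ± 0.39 (adjusted p = 0.116); in both, RIE replicate 1 lay far above the other arrays, and without it Bhlhe40 was at 1.13 and passed. Tgfbr1, the type I receptor, was at 0.72 ± 0.17 (adjusted p = 0.131). Outputs of the Ras and ERK pathway included Dusp6, a phosphatase that inactivates ERK, at -0.79 ± 0.12 (adjusted p = 0.0649), the feedback inhibitor Spry4 at -0.92 ± 0.14 (adjusted p = 0.0650) and the angiogenic factor Vegfa at 1.29 ± 0.24 (adjusted p = 0.0869). Of the 28 measured members of that list, 6 passed adjusted over the list alone, 5 of them lower, and none over all features.

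Ribosomal protein genes were lower in RIE cells as a list, with 26 of 27 members negative, a median of -0.89, 4 past the threshold over all features and 21 adjusted over the list alone (camera adjusted p = 1.77e-15), which did not hold with an estimated correlation (adjusted p = 0.435). Genes of mitochondrial respiration had 22 of 24 members negative and a median of -0.56, with Ndufa5 at -0.79 ± 0.12 and Atp5pb at -0.71 ± 0.13, neither past the threshold. Relative to the array median the lists of heat shock and unfolded protein response genes (22 of 22 negative, median -0.29), cell cycle and DNA replication genes (22 of 28 negative, median -0.22) and sterol and fatty acid synthesis genes (13 of 18 negative, median -0.34) were also lower, although without centring their medians were 0.07, 0.14 and 0.02. With an estimated correlation none of these 4 further lists passed either (adjusted p = 0.435 for respiration and heat shock, and 0.553 for the cell cycle and sterol lists). RIE replicate 1 had the highest median of the RIE arrays in each, with 0.05 for respiration, 0.13 for the cell cycle, 0.05 for sterol synthesis and -0.03 for heat shock. For sterol synthesis RIE replicate 2 was near it, at -0.07. The cell cycle median was -0.38 without RIE replicate 1. Without RIE replicate 4 the medians were -0.55 for ribosomal proteins, -0.35 for respiration, -0.18 for heat shock and -0.19 for sterol synthesis. The sterol list did not pass without RIE replicate 3 or 4, or with these replicates averaged as 1 array (adjusted p up to 0.0816). Examples were the chaperonin gene Hspe1 at -0.97 ± 0.17, the mitotic kinase gene Plk1 at -0.74 ± 0.15, the replication clamp gene Pcna at -0.48 ± 0.10 and the squalene synthase gene Fdft1 at -0.62 ± 0.17, none past the threshold. A list of 31 abundant transcripts outside translation, chosen after the values were seen, had a median of -0.75.

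The second comparison asked the same of RIE-Ras cells. Gadd45b rose by 2.36 ± 0.21 (log2 ± moderated SE, n = 4, limma adjusted p = 0.00954) and Smad7 by 1.39 ± 0.19. Tgif1, a repressor of Smad-dependent transcription, rose by 0.91 ± 0.10, and the matrix genes Thbs1 (thrombospondin 1) and Lox (lysyl oxidase) by 0.87 ± 0.13 and 0.66 ± 0.10, with Thbs1 resting on 4 features that differed in size. The other large rises among named genes were C1ql1 (1.79), Caly (1.61), Neu1 (1.30), Tnxa-ps1 (1.25), Ahsg (1.18), Kcnip3 (1.05), Slc6a5 (1.03) and Cdh13 (0.99), with SE between 0.12 and 0.29. Dusp6 fell by 0.90 ± 0.12 and Plk2 by 0.93 ± 0.12, and the largest falls among named genes were Prdx5, a peroxiredoxin, at -1.38 ± 0.22, Rpl13a at -1.31 ± 0.19 and Cox6c, a cytochrome c oxidase subunit, at -1.07 ± 0.17. Rplp0, Eno1, Hemgn, Nedd8 and Tuba1a fell by between 0.81 and 0.89. Averaged over its features, each gene named so far had the same sign on all 4 RIE-Ras arrays, which the naming rule required of the largest rises and falls. The features of Rplp0 had opposite signs on RIE-Ras replicate 4 (-2.216 and 0.049). A feature of Thbs1 lay below 0 on RIE-Ras replicates 2 and 3 (-0.101 and -0.35). In limma 73 features passed, 52 higher and 21 lower, of which 32 and 15 were named, and 3367 features had an unadjusted p under 0.05 where 870.1 were expected. The count became 12, 0, 0 and 30 without RIE-Ras replicates 1, 2, 3 and 4, 137, 4, 4 and 6 without RIE replicates 1, 2, 3 and 4, 0 when RIE-Ras cells were fitted alone, and 0 after quantile normalization. Without centring, 3657 features passed, 3591 of them higher, with the median feature at 0.29.

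**Figure D1:**
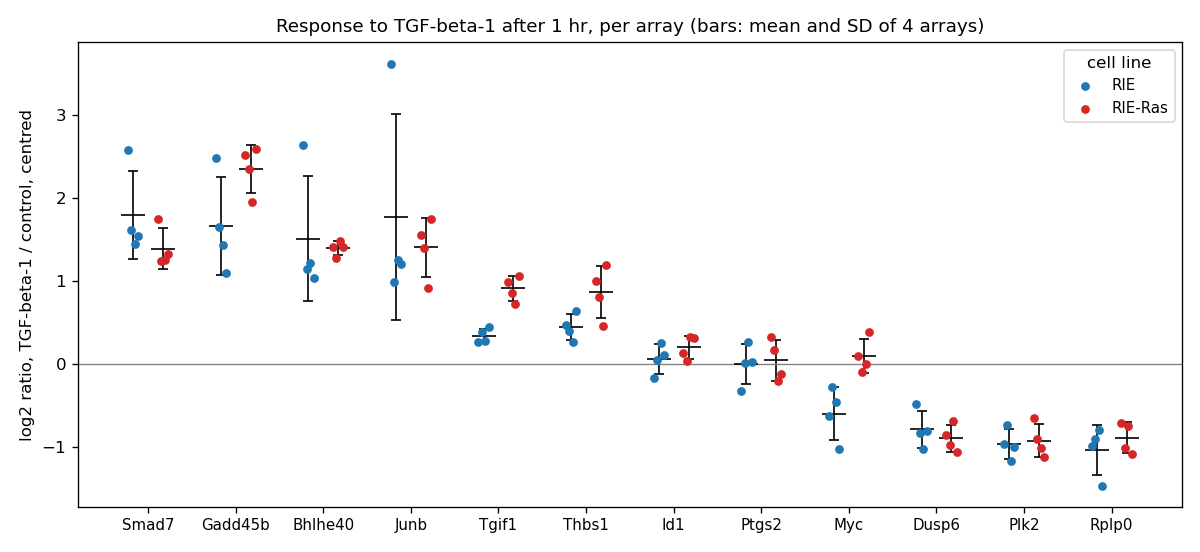
Log2 ratio of TGF-beta-1 treated over control RNA, relative to the array median, for 12 genes; each point is 1 array, and the horizontal marks and bars are the mean and SD of 4 arrays per cell line. Smad7, Gadd45b, Bhlhe40 and Junb lay above 0 on all 8 arrays, and Dusp6, Plk2 and Rplp0 below 0 on all 8.

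The TGF-beta and Smad early targets were higher as a list in RIE-Ras cells too (16 of 26 positive, median 0.22, camera adjusted p = 0.00905), with 3 members past the threshold over all features, Gadd45b, Tgif1 and Smad7, and 10 adjusted over the list alone, 9 of them higher. With an estimated correlation the adjusted p was 0.548. Bhlhe40 was at 1.40 ± 0.24 (adjusted p = 0.0539), Rhob, a small GTPase, at 0.68 ± 0.12 (adjusted p = 0.0539) and Junb at 1.41 ± 0.39 (adjusted p = 0.117). In the receptor and Smad list Tgfb3 was at 1.00 ± 0.20 (adjusted p = 0.0678). Members of the NF-kappaB and inflammatory list had a median of -0.13, and 5 of 25 passed adjusted over the list alone, 2 higher and 3 lower. The lower ones were the inhibitor gene Nfkbia at -0.57 ± 0.10, the chemokine gene Cxcl1 at -0.99 ± 0.18 and Cebpd at -0.81 ± 0.16, and the list did not pass (camera adjusted p = 0.0755). Of 28 measured Ras and ERK outputs only Dusp6 passed over all features, and 6 adjusted over the list alone, 5 of them lower. Spry4 was at -0.74 ± 0.14 (adjusted p = 0.0595) and Dusp5 at -0.51 ± 0.10 (adjusted p = 0.0595). In the mesenchymal and matrix list 7 of 25 members passed adjusted over the list alone, 3 higher and 4 lower, with Vim at -1.34 ± 0.26 and S100a4 at -1.15 ± 0.23 among the lower ones.

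Ribosomal protein genes were lower in RIE-Ras cells as well (26 of 27 negative, median -0.80, 1 past the threshold over all features and 22 adjusted over the list alone, 21 of them lower), and so were genes of mitochondrial respiration (22 of 24 negative, median -0.36), with an adjusted p of 0.499 and 0.548 under an estimated correlation. The sterol and fatty acid list was lower relative to the array median (12 of 18 negative, median -0.23, camera adjusted p = 0.0290), with Fdps at -0.73 ± 0.17, and its median was 0.05 without centring. With an estimated correlation the adjusted p of the sterol list was 0.548, and the list did not pass without RIE-Ras replicate 2 or 4 (adjusted p up to 0.164). The 31 abundant transcripts outside translation had a median of -0.69.

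**Figure D2:**
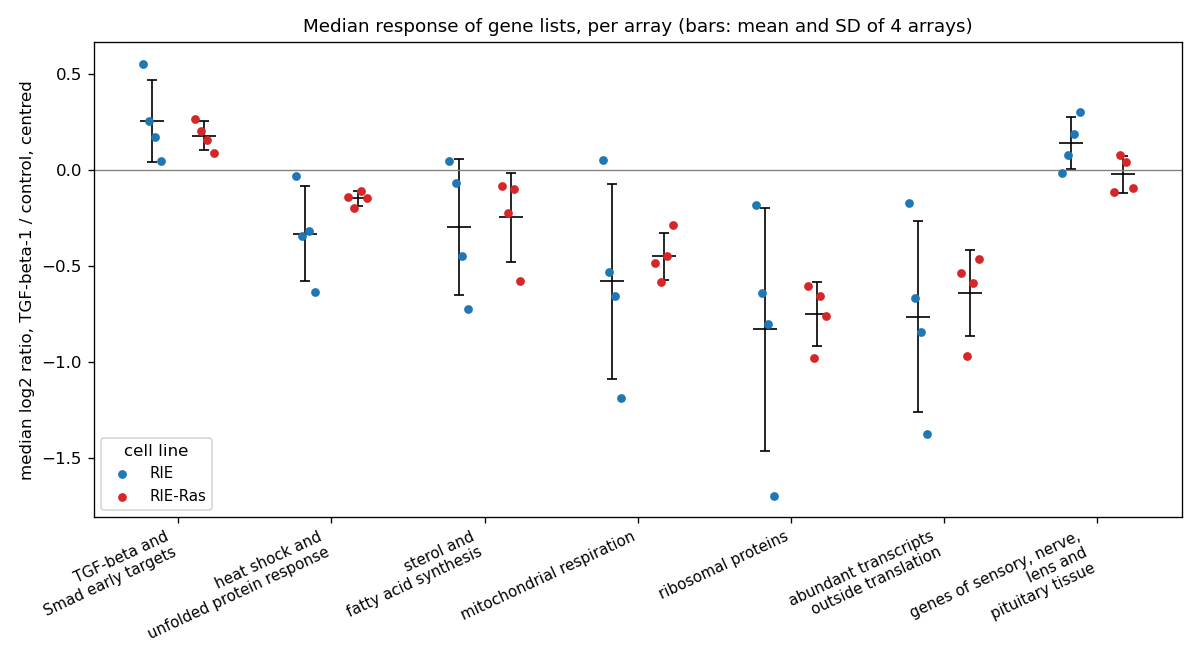
Median log2 ratio of TGF-beta-1 treated over control RNA over the measured members of 7 gene lists, relative to the array median; each point is 1 array, and the marks and bars are the mean and SD of 4 arrays per cell line. The ribosomal protein medians ran from -0.18 to -1.69 in RIE cells and from -0.60 to -0.98 in RIE-Ras cells, and abundant transcripts outside translation lay below 0 on all 8 arrays.

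The third comparison asked whether the response differed between the lines. By limma no feature passed in the contrast of RIE-Ras minus RIE, and 1857 had an unadjusted p under 0.05 where 870.1 were expected; the smallest adjusted p was 0.112. On 1305 features, 7.50% of all, the arrays of the 2 lines did not overlap, where chance gives 2.86%. The named genes with the smallest p, none of which passed (adjusted p = 0.228 for each), were Gnao1 (difference 1.16 ± 0.17), Zfp952 (1.19 ± 0.18), Ap4s1 (1.43 ± 0.22), Prss23 (0.87 ± 0.14) and Clcn7 (1.19 ± 0.19) on the higher side in RIE-Ras cells. On the lower side they were Hemgn (-1.06 ± 0.15), Ica1l (-1.33 ± 0.24), Mgst3 (-0.80 ± 0.15), Gbx2 (-0.73 ± 0.14) and Hoxc5 (-1.02 ± 0.20), and the features averaged for Gbx2 differed in size. For the canonical targets the difference was -0.41 ± 0.27 for Smad7, -0.37 ± 0.55 for Junb, 0.28 ± 0.37 for Klf10 and 0.57 ± 0.14 for Tgif1, with adjusted p between 0.246 and 0.856. Myc, which TGF-beta represses in many epithelial cells, was at -0.60 ± 0.14 in RIE and 0.09 ± 0.14 in RIE-Ras cells, a difference of 0.70 ± 0.20 (adjusted p = 0.311). Tgfb2 (0.76 ± 0.16), Tgfb3 (1.28 ± 0.29), Bub1 (1.11 ± 0.22), Lox (0.69 ± 0.15), Rpl27 (1.11 ± 0.23) and Cebpd (-0.91 ± 0.23) were among the members of fixed lists with small p. None passed over all features. Adjusted over the list alone, 3 members of the receptor and Smad list passed, with 2 ribosomal, 1 cell cycle and 1 mesenchymal member. All of these had positive differences. Id1, Ptgs2 and Tgfb1 differed by 0.14 ± 0.15, 0.05 ± 0.19 and -0.46 ± 0.27, where Ptgs2 is the average of 2 features whose means had opposite signs in each line. None of the 19 lists passed by camera, with either correlation, or by fry for a shift in one direction. Without RIE replicate 1, 1 feature and 5 lists passed, among them the lists of the cell cycle, heat shock, ribosomal proteins and respiration, each higher in RIE-Ras cells. The feature count was 1 without RIE-Ras replicate 3, 2 without RIE-Ras replicate 4, and 134 with array weights, which gave RIE replicate 3 a weight of 8.70.

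The responses of the 2 lines shared 4 calls. Smad7 and Gadd45b were higher in both, where 0.00896 shared features were expected of independent calls, and Plk2 and Rplp0 were lower in both, where 0.0121 were expected; both expectations ignore that the lines share 1 estimate of spread per feature, which favours shared calls. Of the 13 features past the threshold in RIE cells 12 had the same sign in RIE-Ras cells, and of the 73 in RIE-Ras cells 55 had the same sign in RIE cells. Across all features, which are not independent replicates, the mean ratios of the lines correlated with Pearson r = 0.256 and Spearman rho = 0.292. No arrays are shared between the lines, but treated RNA was in the same channel on all 8 arrays, so dye effects of single features may be part of the overlap by an unknown amount. Quantile normalization left no shared call and gave r = 0.324.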

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

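The tests of abundant transcripts, translation factors and genes of other tissues were fixed before their results were seen; those of position on the array and of whole-number signals were chosen after. In 198 sets of 4 arrays, over 77 genes named in the text, the gene lists reported and measures of the arrays, 13 had an array far from the other 3, which is 6.57%, where chance alone gives about 1 in 20. RIE replicate 1 was that array for Junb (3.63 against 0.99 to 1.26 on the others), Bhlhe40 (2.65), Smad7 (2.59), Cebpd (0.65), Tnxa-ps1 (0.52) and Ccl2 (-0.16). RIE replicate 4 was it for Hes1 (0.26), Insig1 (-1.25) and the share of features below -1 after centring (7.29%). RIE-Ras replicate 4 was it for Prdx5 (-2.15), Ccl2 (0.23) and the median of the cell cycle list (0.22), and RIE-Ras replicate 1 for Smad7 (1.75). In the contrast of the lines, fry found change in either direction among the receptors and Smad proteins of TGF-beta signalling (adjusted p = 0.00985) and the NF-kappaB and inflammatory genes (adjusted p = 0.0102). Neither list shifted one way (adjusted p = 0.314 and 0.577 by fry). The test for either direction does not set a list against other genes, and 15 of the 19 lists passed it in each line.

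Ribosomal protein and respiration transcripts were lower in both lines. With a ratio that falls with spot brightness other abundant transcripts would be lower too. The 31 measured had medians of -0.755 in RIE and -0.692 in RIE-Ras cells, below 0 on all 8 arrays. These medians also lay below a bound computed from the ribosomal medians of the same data, -0.445 and -0.398. The rule for that bound was fixed before this list was tested, but the list was chosen after the values were seen. If the translation machinery had changed, translation factors and other transcripts of its class would lie further below, but the median of their mean ratios stood above that of the abundant transcripts by 0.205 and 0.361 (mean of the differences per array 0.309 ± 0.116 and 0.262 ± 0.072, SE, n = 4). A brightness bias is therefore a candidate explanation, and the factors did not lie further below. The test cannot decide on the translation machinery, since no intensities were used. The factors were lower themselves, with medians of -0.55 in RIE and -0.33 in RIE-Ras cells. Ribosomal proteins lay below the abundant transcripts, at -0.891 and -0.795. A biological fall of abundant transcripts in general stays open as well. Whether a bias of dim spots is a source of rises such as C1ql1 and Slc6a5 in RIE-Ras cells stays open: 118 genes picked by symbol prefixes of sensory, nerve, lens and pituitary genes had a median of -0.012 there (0.125 in RIE cells), but they went both ways, with 61 negative, and were not shown to be dim.

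RIE-Ras replicate 1 had 8.16% of features below -1 after centring, against 0.849% to 2.77% on the other RIE-Ras arrays. Fold changes on it repeated at a few values, 969 features lying on 11 of them, spaced as quotients of small whole numbers times one unit would be; 469 of these lay at a rise of 1.18-fold, outside this tail, and 138 features of RIE-Ras replicate 2 and 59 of replicate 3 lay at repeated rises. With the unit chosen on odd-numbered features (1.177), 53.14% of the fold changes beyond -2.5 on even-numbered features were quotients of whole numbers up to 20 times that unit, and 19.69% at most for 350 other units. A first form of this test, with the unit at 1.18 as printed to the hundredth, had matched 4.32%, against 14.32% for the best of 36 other units, and the finer unit was adopted after that result. Dim spots with signals of a few units may therefore make up much of this tail; without features at repeated values 157 features passed in RIE-Ras cells.

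Part of RIE replicate 1 gave higher ratios than the rest, with 9.10% of its variance between 35 position blocks and 0.280% at most in 100 shuffles of positions, which makes position a candidate source of its spread. RIE-Ras replicate 2 had 6.83% between blocks and the other arrays 1.27% to 2.19%. RIE replicates 3 and 4 correlated across features with r = 0.688, while no other pair of arrays passed 0.391. That value was for a pair from different lines, RIE replicate 4 and RIE-Ras replicate 2. RIE replicate 1 correlated with RIE replicates 2, 3 and 4 at 0.269, 0.129 and 0.084. RIE-Ras replicate 1 correlated with RIE-Ras replicates 2, 3 and 4 at -0.041, -0.015 and 0.161 (Spearman 0.280, 0.248 and 0.279).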

How the results depend on the processing

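Position correction and the averaging of RIE replicates 3 and 4 were chosen after seeing the data. The count of features past the threshold in RIE cells (13) was 4061 without centring, 87 with equal spread, 95 after quantile normalization, 6539 with array weights, 1 with RIE cells alone, 132 at an adjusted p under 0.10, 7 after position correction, 1 with RIE replicates 3 and 4 as 1 array, and 0 to 30 without 1 array. In RIE-Ras cells (73) it was 3657, 10 and 0 under the 3 scalings, 157 without features at repeated values, 0 with RIE-Ras cells alone, 673 at an adjusted p under 0.10, 128 after position correction, 4 with RIE replicates 3 and 4 as 1 array, and 0 to 137 without 1 array. In the difference (0) it was 1 without centring, 1 with limited values, 1 after position correction, 134 with array weights and 0 to 2 without 1 array. The other alternatives run for these counts kept them within 1.5 times, although with each probe on its own 7 of the 13 RIE calls and 67 of the 73 RIE-Ras calls remained; the replicate block was run only for the difference and the lists. Of the lists, 0 passed with an estimated correlation in RIE (6) and RIE-Ras cells (4), by fry 1 passed in RIE-Ras cells, the ERK outputs (adjusted p = 0.0222) and none of those 4, and in RIE cells the cell cycle and sterol lists were lost and ERK outputs and apoptosis regulators gained, and 0 to 5 passed in the difference (0) without 1 array. The correlation of the effects was 0.324 after quantile normalization. The cause was not tested, except that a looser threshold and the missing centring act by construction; fewer arrays do not account for the higher counts without RIE replicate 1. Of 2108 recomputed values of named genes 1623 kept their side of the threshold, 351 lost it and 134 gained it, and 21 changed sign, none of them past the threshold. The values that kept their side include those of genes that passed in neither fit. Each gene past the threshold in the main fit lost it under 4 (Gadd45b in RIE-Ras cells) to 13 (Coa4 in RIE cells) of 19 alternatives. Smad7 stayed between 1.51 and 2.27 in RIE and between 1.27 and 1.68 in RIE-Ras cells, past the threshold under 11 and 8 of 19 alternatives. The TGF-beta, ribosomal and respiration lists passed by camera with the preset correlation in both lines under all 18 alternatives that were run, with the TGF-beta median between 0.09 and 0.58 in RIE and 0.21 and 0.51 in RIE-Ras cells. Same-numbered arrays of the lines did not deviate together (correlations 0.065, -0.041, -0.024 and -0.054). Differently numbered arrays gave -0.15 to 0.179, so these values do not decide whether the numbers pair the samples. With the replicate block 0 features and 0 lists passed in the difference, 7 lists in RIE and 4 in RIE-Ras cells. Filters on missing values were void, since none was missing, and robust eBayes and single probes were not run for the lists. Signal over background, which limits dim features, was not measured here.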

Other observations

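The proteasome list and 2 unnamed features were examined only after their values were seen. The count of RIE calls rests on signs shared by 4 arrays. Over the 8 sign patterns of the arrays of a line, the real pattern gave 13 features in RIE cells and the highest other 0, and in RIE-Ras cells it gave 73 and the highest other 9; in each line 1 of 8 patterns reached the real count, and 8 patterns are too few for a share under 0.05. For the contrast of the lines, 2 of the 35 splits of the 8 arrays gave as many features at an unadjusted p under 0.05 as the real 1857, the other giving 2009, so chance is not excluded. That split set RIE replicate 1 and RIE-Ras replicates 1, 3 and 4 against the other arrays.

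Epithelial junction and keratin genes had 0 of 21 members past the threshold in either line, with medians of 0.02 in RIE and 0.06 in RIE-Ras cells. Prostaglandin genes had 0 of 17, and Ptgs2, the inducible cyclooxygenase, was at -0.01 ± 0.13 and 0.04 ± 0.13, averages of 2 features of opposite sign (0.22 and -0.23 in RIE, 0.28 and -0.19 in RIE-Ras cells). The Id and BMP-type list had medians of -0.04 and 0.01 over 11 members, with Hes1 at 0.77 ± 0.16 in RIE cells (adjusted p = 0.111; its 2 features were at 1.04 and 0.49). The 28 immediate early genes had medians of 0.08 and -0.05, and Zfp36l1, an mRNA decay factor, was at -0.69 ± 0.17 and -0.85 ± 0.17, neither past the threshold. Apoptosis regulators had medians of -0.07 and -0.08, and Birc5 was at -0.58 ± 0.12 in RIE-Ras cells (adjusted p = 0.0642). Intestinal differentiation genes had medians of 0.09 and 0.03. Markers of fibroblasts and smooth muscle had medians of -0.02 and 0.09, and those of immune and endothelial cells 0.15 and -0.06. In RIE cells the medians of the mesenchymal, NF-kappaB, receptor and ERK output lists were -0.15, 0.0099, 0.0020 and -0.0064. In RIE-Ras cells those of the cell cycle, heat shock, mesenchymal, receptor and ERK output lists were -0.17, -0.14, 0.04, 0.10 and -0.09. All are relative to the array median, and none of the lists in this paragraph passed by camera in the line for which its median is given. Median and mean differed in sign for the Id, epithelial, receptor and NF-kappaB lists in RIE cells, and for the immediate early, mesenchymal and fibroblast lists in RIE-Ras cells.

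The 34 genes with symbol prefixes of proteasome subunits, a list chosen after the values were seen, had medians of -0.43 in RIE and -0.28 in RIE-Ras cells (camera adjusted p = 6.46e-08 and 1.16e-05 with the preset correlation over 4 such lists; unadjusted p = 0.113 and 0.179 with an estimated correlation). Without Psmc3ip, a recombination factor that shares only the prefix, the medians were -0.44 and -0.29. The median of the 34 genes was 0.09 on RIE replicate 1, -0.91 on RIE replicate 4 and -0.33 and -0.44 on the other RIE arrays. The largest rise past the threshold was of an unnamed feature in each line, a different one in each. The rise was 3.21 ± 0.33 in RIE and 2.58 ± 0.22 in RIE-Ras cells, and both features were singled out after their values were seen.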
